A study of Mus musculus with 8 samples.

How the data were processed

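RNA from whole spleens of 8-week-old mice was hybridised to Affymetrix mouse expression arrays, 1 spleen per array, with 4 arrays of Nix-null mice and 4 of wild-type mice. Nix is the protein encoded by Bnip3l. Per the labels' protocols, RNA was extracted with Trizol, purified on columns, checked on a Bioanalyzer, not pooled, and labelled with biotin in a single labelling cycle. Per the labels, the samples are separate animals of each genotype. Arrays are named here by genotype and by the number in their titles: Nix_KO 10, 2, 3 and 6, and WT 3, 4, 5 and 6.

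The authors deposited 1 intensity per probe set and array. Per the submitters' processing notes the intensity values come from GCRMA, which corrects background, normalizes between arrays and summarises the probes of a probe set; its version is not given in the sources used here. The deposited intensity values are on a linear scale, with array medians from 28.84 to 30.61 and highest values from 75396.4 to 83020.2. The step that made them linear is not given in the sources used here, nor is any scaling after GCRMA. The design had assumed log2 values, so the intensities were log2-transformed before any other step, with no offset because all were above 0. GCRMA pulls weak probe sets towards a common low level, so a fold change of a weak probe set depends on that correction. The precision of every comparison is limited by the number of arrays, 4 per group.

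The deposited table held 45101 probe sets. The 64 control probe sets were left out, and a probe set was tested where its log2 intensity was at least 5 in at least 4 of the 8 arrays, whichever they were. This kept 22347 of 45037 probe sets. Probe sets were named from the platform annotation: 34945 had 1 gene symbol, 932 had several and 9160 had none. Of the single-gene probe sets, 34754 had an Entrez identifier in the mouse gene table (assembly GRCm38.p6), and 0 symbols differed from that table. The table was used only for names and for which genes neighbour each other, since no genome build goes with the arrays' files. A gene was represented by its single-gene probe set with the highest mean over all 8 arrays, which gave 11027 genes.

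Nix-null and wild-type arrays were compared on log2 intensities with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets or all genes tested and a threshold of 0.05 on the adjusted p. Every single-gene or single-probe-set adjusted p below is from this limma fit. Fold changes are Nix-null over wild type, and errors of log2 fold changes are standard errors. Fixed gene lists, 14 of pathways and 12 of cell markers, were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 26 lists, and again with the correlation estimated from the data. Camera compares a list with the other genes. Genes near Bnip3l, within 20 Mb, were compared with the rest by Fisher's exact test. Single differences between lists or probe sets were tested by exact permutation over the arrays, where 0.0286 is the smallest two-sided p that 4 against 4 can give. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

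The genes named were chosen by a rule fixed, like the lists, the design and the first set of alternatives, before the data were examined. It takes Bnip3l, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, leaving out unnamed clones. It adds up to 4 members of each list with the smallest adjusted p past the threshold, and a set of erythroid and cell death genes named whether or not they passed. Bax was not named by the annotation and was not analysed here. The rule gave 123 genes at the gene level, of which 52 had more than 1 probe set past the filter. For 15 of these the probe sets differed in call, and for 0 they were called in opposite directions. The 15 were Bcl2, C1qb, Cd247, Cd8a, Creb3l2, Cycs, Egln1, Fscn1, Hk1, Mcl1, Ndufa5, Thrsp, Trim34a, Wipi1 and Xbp1. Other genes named as exceptions within a list, as neighbours of Bnip3l or as members of a family were chosen after their values were seen.

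The fit and the list test were tested on simulated data for this comparison, with 11027 genes and 200 of them changed. The fit recovered 4.48% of 67 genes changed 1.5-fold, 50.7% of 67 changed 2-fold and 97% of 66 changed 4-fold, and 5.61% of calls were false. With no gene changed it made 0 calls. A list shifted down by 1 log2 unit was called, with 0 other lists. The simulated genes were independent of each other, unlike those of the lists here (estimated correlation 0.7 for the cell cycle list). The list result therefore does not cover lists of correlated genes. Of the real genes 38.3% passed, a larger share than was changed in the simulation, so its recovery rates need not hold here.

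The numbers 3 and 6 occur in the titles of both genotypes. Alternatives fixed in advance were no filter or a stricter one, quantile normalization repeated, median centring, an intensity trend with robust estimation, array weights, a plain unequal-variance test, the title number as a block, each array left out in turn, other thresholds, the mean of a gene's probe sets, an estimated correlation in camera, a smaller window around Bnip3l and a floor on low values. Added after seeing the data were a Kdm5d covariate, the arrays with pancreatic signal left out, the arrays with both Xist and Y-linked signal left out, and other counts of genes near Bnip3l. No column of the deposited table was without a sample. The smallest median absolute log2 difference between any 2 arrays was 0.153, so no 2 columns held the same values.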

Results

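Gene expression in spleens of 8-week-old mice lacking Nix was compared with that of wild-type spleens, with 4 animals and 4 arrays per genotype. The series title places the comparison in apoptosis and erythropoiesis: Nix (Bnip3l) is a mitochondrial protein of the BCL2 family with a known part in clearing mitochondria from maturing red cells. In each array 48.6% to 49.3% of probe sets had a log2 intensity of at least 5.

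Signal of the targeted gene was present in all 8 arrays. Of its 3 probe sets, called A, B and C here, A read a log2 intensity of 12.64 ± 0.36 (SD, n = 4) in Nix-null and 12.21 ± 0.26 (SD, n = 4) in wild-type spleen. For B the levels were 10.10 ± 0.57 and 10.59 ± 0.04, and for C 10.26 ± 0.54 and 9.68 ± 0.22 (SD, n = 4 each). None of the 3 differences passed the test, with log2 differences of 0.43, -0.50 and 0.58 and limma adjusted p = 0.158, 0.164 and 0.117. The probe sets moved apart: the change of B minus that of A was -0.92 and minus that of C -1.08 (exact permutation p = 0.0286 for each, the smallest possible, adjusted p = 0.0429 over the 3 pairs). The change of C minus that of A was 0.15 (exact permutation p = 0.343). This comparison of pairs was not in the fixed design, and the 2 pairs that passed share B, so they are not independent. All 3 probe sets are annotated jointly to Bnip3l and its pseudogene Bnip3l-ps, and the deleted part of the gene is not given in the sources used here. These probe sets therefore did not check the genotype labels, and every direction below rests on arrays labelled Nix-null and wild type.

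**Figure D1:**
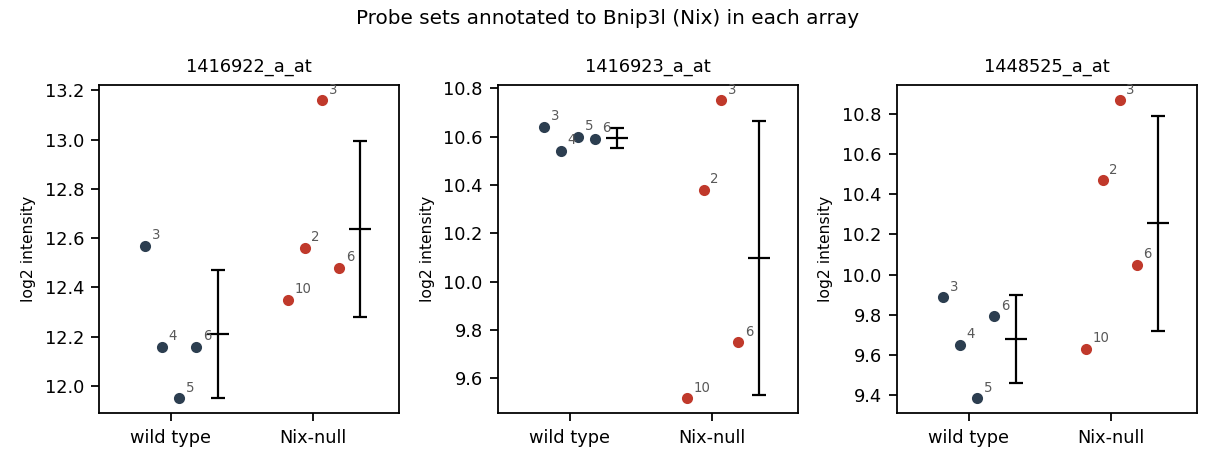
Log2 intensity (vertical axis) of the 3 probe sets annotated to Bnip3l (A, B and C from left to right), with a point per array marked by its title number, and bars showing the mean ± SD of 4 arrays per genotype. Nix-null means were 12.64, 10.10 and 10.26 and wild-type means 12.21, 10.59 and 9.68, with overlapping arrays in each panel.

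Nix-null spleens had higher levels of red cell and cell division genes and lower levels of lymphoid and stromal genes, counted gene by gene; as lists they passed only with a preset correlation between genes, and 0 of 26 lists passed with an estimated one. Of 11027 genes, 4227 changed, 1570 higher and 2657 lower, and 816 of the higher and 841 of the lower ones by at least 2-fold (limma, adjusted p under 0.05). Where arrays read below a log2 intensity of 5, folds are given as lower bounds with those values set to 5, and such genes have no exact rank. Large rises included those of Ccnb1ip1, a cyclin B1 interacting protein (at least 9.7-fold, wild-type mean 3.52), Plek2, a pleckstrin family member (at least 9.74-fold), and Icam4, a red cell adhesion molecule (log2 2.91 ± 0.55 SE). Adamdec1, a secreted metalloprotease of the ADAM family, fell at least 32.9-fold, from 10.04 ± 0.32 to near background (2.99 ± 0.63, SD, n = 4 each), and Ang, a secreted ribonuclease, at least 2.4-fold (Nix-null mean 2.43). The limma adjusted p was 0.000144 for Ccnb1ip1, 2.04e-06 for Adamdec1 and 0.00145 for Ang. Without the filter on dim probe sets Ang was represented by another probe set, whose difference was 0.005 (limma adjusted p = 0.989).

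Other large rises, chosen like these by the deposited values, were those of Tlcd4, Apol8, Lmbr1, Ypel4, Depdc1a and Diaph3, from 7.01-fold to 8.77-fold, and of St6galnac1 (at least 3.12-fold). Other large falls were those of Pcdh17, Trim34a, Ifi213 and Trim30d, from 4.96-fold to 5.66-fold, and of Dph5, Spata5l1, Trim12a and Dzip1, at least 7.22-fold, 6.18-fold, 4.76-fold and 3.44-fold. The sizes of some falls rest on single arrays: without Nix_KO 10 the log2 change of Trim34a was -1.60 in place of -2.47, of Trim12a -1.58 in place of -2.43 and of Trim30d -1.62 in place of -2.31, and without Nix_KO 2 that of Dph5 was -2.26 in place of -2.96. These 4 kept their call whichever single array was left out, but not under a plain unequal-variance test (adjusted p = 0.151, 0.156, 0.127 and 0.0961). Of all 11027 genes, passing or not, 4363 had Nix-null and wild-type arrays that did not overlap, where chance gives a share of 0.0286, or 315 genes. At the probe set level 6711 of 22347 changed, 2789 higher and 3922 lower. Without WT 6 alone 3996 changed (2107 lower) and without WT 4 alone 4075 (2096 lower). The median over all tested genes was -0.15, so small falls were counted against a shifted centre. With each array centred on its median, that median was -0.025 and 47.8% in place of 37.1% of the changed genes were higher (1886 higher, 2059 lower). Without the arrays Nix_KO 3, WT 3 and WT 5, chosen after seeing the data for their pancreatic signal, 1684 genes passed (846 higher, 838 lower) and 690 probe sets (500 higher, 190 lower).

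Genes of red cell development rose together. Of 20 tested erythroid regulators and receptors 13 rose and 3 fell, with a median log2 change of 1.62. Gata1, the central transcription factor of red cell precursors, rose 4.60-fold (log2 2.20 ± 0.38 SE, limma adjusted p = 0.00232). The erythropoietin receptor gene Epor rose 4.17-fold, the transferrin receptor gene Tfrc 3.74-fold, the transcription factor genes Klf1 3.87-fold, Nfe2 4.68-fold and Sox6 6.69-fold, Mybl2 3.99-fold and Trim10 3.93-fold. The 3 that fell were Bcl11a (log2 -0.64), known for silencing fetal globin, Stat5b (-0.60) and Ldb1 (-0.42). Adjusted over the list alone, 13 rose and 5 fell. The list passed camera at the preset correlation (adjusted p = 0.000425) but not with its correlation estimated (adjusted p = 0.46 with an estimated correlation).

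Of 26 tested genes of the red cell membrane and surface, 24 rose and 1 fell, adjusted over the list alone too, with a median log2 change of 2.10. Ackr1, the Duffy antigen receptor, rose 5.61-fold, Epb42, a band 4.2 membrane skeleton protein, 5.14-fold, Tmod1, which caps actin filaments, 3.96-fold and Gypc, glycophorin C, 3.73-fold. Slc4a1, the band 3 anion exchanger, rose from a high wild-type level (log2 1.13 ± 0.19 SE, limma adjusted p = 0.00224). The 1 that fell was the glucose transporter gene Slc2a1 (log2 -1.05). The list's mean log2 intensity was 11.81 ± 0.23 in Nix-null and 9.99 ± 0.76 in wild-type arrays (SD, n = 4 each). Camera gave adjusted p = 4.81e-13 at the preset correlation and adjusted p = 0.39 with an estimated correlation.

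Of 21 tested genes of haemoglobin, haem and iron handling, 19 rose and 0 fell, adjusted over the list alone too, with a median log2 change of 1.54. Fech, which inserts iron to form haem, rose 3.16-fold, and Uros and Ppox, enzymes of haem synthesis, 3.54-fold and 3.72-fold. Alas2, the first enzyme of erythroid haem synthesis, rose 2.37-fold (log2 1.25 ± 0.20 SE, limma adjusted p = 0.00196), and Abcb6, a porphyrin transporter, 4.2-fold. The camera result was adjusted p = 1.04e-12 at the preset correlation and adjusted p = 0.39 with an estimated correlation.

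All 45 tested genes of the cell cycle and DNA replication rose, adjusted over the list alone too, with a median log2 change of 1.70 and a range from 0.91 to 2.49. Mki67, a marker of dividing cells, rose 4.45-fold (log2 2.16 ± 0.40 SE, limma adjusted p = 0.00313). Top2a, topoisomerase II alpha, rose 3.05-fold, the spindle genes Nusap1 and Tpx2 5-fold and 4.96-fold, and the replication licensing gene Mcm4 2.57-fold. Camera gave adjusted p = 3.73e-27 at the preset correlation and adjusted p = 0.39 with an estimated correlation. Cdkn1a, an inhibitor of cell division, differed by -0.65 ± 0.26 SE (limma adjusted p = 0.0726). It passed with array weights (-0.69, limma adjusted p = 0.0423) and without Nix_KO 10 (-0.78, 0.0471), within a range from 0.0423 to 0.189 over the alternatives.

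Cell death genes moved both ways, as did tested genes in general, of which 38.3% passed (1570 higher and 2657 lower of 11027). Neither the BCL2 family list nor the caspase and death factor list passed camera, which compares a list with the other genes. Of 19 tested members of the BCL2 family other than Bnip3l, 2 rose, 5 fell and 12 did not pass, adjusted over the list alone too. Bcl2l1, encoding the survival protein BCL-XL, rose 2.71-fold (log2 1.44 ± 0.23 SE, limma adjusted p = 0.00186), and Bcl2l13 rose 2.10-fold. The death-promoting BH3-only genes Bmf and Pmaip1 fell 2.54-fold and 2.05-fold, and Bcl2, another survival gene, fell 1.87-fold (limma adjusted p = 0.036), a call lost when any 1 array other than Nix_KO 10 was left out (without Nix_KO 2 the log2 change was -0.60 in place of -0.91). Mcl1, Bak1 and Bnip3, the closest relative of Bnip3l, differed by -0.27, -0.08 and -0.24 (limma adjusted p = 0.176, 0.768 and 0.21). The probe sets of Mcl1 differed in call: averaged, they gave -0.60 (limma adjusted p = 0.0161, within a range from 0.0161 to 0.584 over the alternatives). The list's median was -0.15 (-0.145 before rounding, camera adjusted p = 0.747, and adjusted p = 0.83 with an estimated correlation).

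Of 26 caspases, death receptors and mitochondrial death factors, 2 rose, 4 fell and 20 did not pass (1 and 4 adjusted over the list alone). Htra2, a mitochondrial protease, rose 1.84-fold and Cycs, cytochrome c, 1.39-fold. Tradd, Birc3 and Tnfrsf1a, of tumour necrosis factor receptor signalling, fell 1.73-fold, 2.06-fold and 1.6-fold. Casp9 differed by -0.13 ± 0.16 SE (limma adjusted p = 0.544). The list's median was -0.17 (camera adjusted p = 0.667, and adjusted p = 0.83 with an estimated correlation). Of 16 p53 targets 1 rose, Gadd45a (3.97-fold), and 2 fell, Zmat3 (1.88-fold) and Pmaip1, adjusted over the list alone too. Their median was -0.08, with 2 scalings giving the opposite sign, while camera's direction was up (adjusted p = 0.857, and adjusted p = 0.9 with an estimated correlation).

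**Figure D2:**
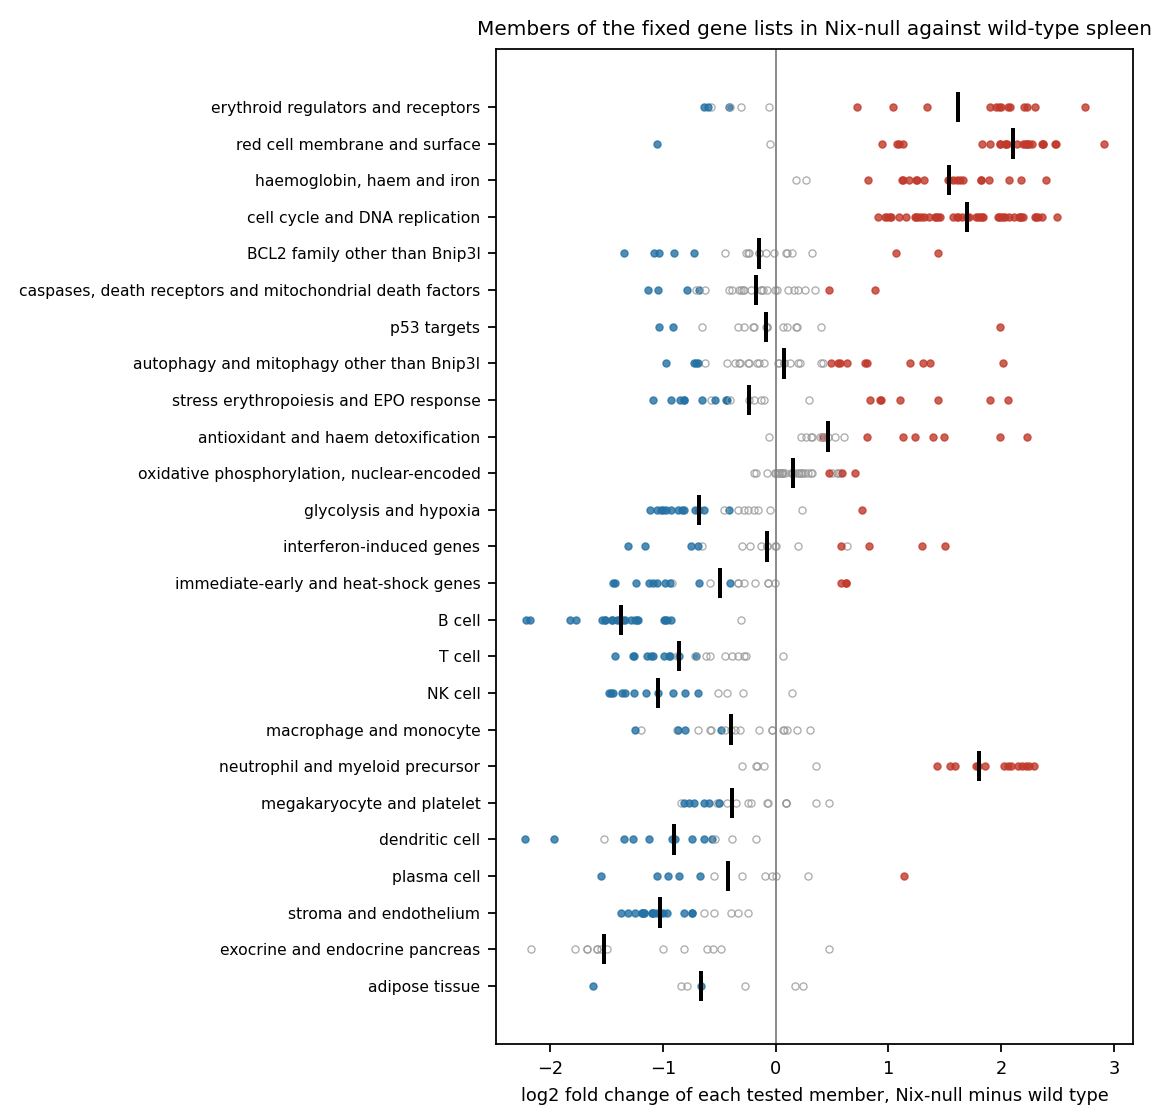
Log2 fold change of each tested gene (horizontal axis, Nix-null minus wild type) by gene list, with filled points for genes past the adjusted p threshold of 0.05 (red higher, blue lower), open points for the others and a black bar at the list's median. Medians were 2.10 for the red cell membrane, 1.70 for the cell cycle and 1.8 for neutrophil genes, against -1.37 for B cell genes.

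Of 19 genes of antioxidant defence and haem detoxification, 11 did not pass and 0 fell, while 8 rose, adjusted over the list alone too. These included the glutathione synthesis genes Gclm (3.96-fold) and Gclc (2.81-fold), the quinone reductase gene Nqo1 (4.68-fold) and the mitochondrial peroxiredoxin gene Prdx3 (2.63-fold). Hmox1, which breaks down haem, differed by 0.32 ± 0.28 SE (limma adjusted p = 0.389). The list passed camera at the preset correlation (adjusted p = 2.38e-06, and adjusted p = 0.39 with an estimated correlation). Of 33 autophagy and mitophagy genes other than Bnip3l, 10 rose and 4 fell, adjusted over the list alone too. Atg4a rose 4.05-fold, Wipi1 2.58-fold, Foxo3 2.47-fold and Atg9a 2.29-fold. Their median was 0.07 (camera adjusted p = 0.091, and adjusted p = 0.46 with an estimated correlation).

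Of 23 genes of stress erythropoiesis and the erythropoietin response, 7 rose and 9 fell (7 and 10 adjusted over the list alone), among them Pim1 (2.14-fold higher) and Cdc25a (1.90-fold higher) beside Epor and Tfrc. Their median was -0.24 (-0.235 before rounding) and camera's direction up (adjusted p = 0.747, and adjusted p = 0.83 with an estimated correlation). Of 35 nuclear genes of oxidative phosphorylation 3 rose, Ndufa5 (1.63-fold), Ndufv2 (1.5-fold) and Cycs, and 0 fell. The count was 0 adjusted over the list alone, and camera gave adjusted p = 0.00487 at the preset correlation and adjusted p = 0.77 with an estimated correlation. Of 23 glycolysis and hypoxia genes 13 fell and 1 rose (15 and 1 adjusted over the list alone): Pkm fell 2.17-fold, Hif1a 2.00-fold and Egln1 1.64-fold, while Hk1, a hexokinase, rose 1.70-fold. That list had camera adjusted p = 0.00477, and adjusted p = 0.55 with an estimated correlation.

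Of 18 interferon-induced genes 4 rose and 4 fell (5 and 4 adjusted over the list alone), with Rsad2 2.84-fold and Ifit1 2.46-fold higher and Cxcl10 2.48-fold and Ddx58 2.24-fold lower. Their median was -0.08, with the opposite sign under 2 scalings, and camera's direction was up (adjusted p = 0.667, and adjusted p = 0.87 with an estimated correlation). Of 22 immediate-early and heat-shock genes 10 fell and 3 rose (11 and 3 adjusted over the list alone), including Zfp36 (2.69-fold), Klf2 (2.37-fold), Junb (2.13-fold) and Nr4a1 (2.07-fold), all lower. Camera gave adjusted p = 0.0857 at the preset correlation and adjusted p = 0.73 with an estimated correlation.

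Markers of B cells were lower in Nix-null spleen: 21 of 22 fell, adjusted over the list alone too, with a median log2 change of -1.37. Fcer2a, the low-affinity IgE receptor, fell 4.53-fold, Cd79a, part of the B cell receptor, 2.85-fold, Cd40 2.65-fold and the kinase gene Blk 2.52-fold. Of 21 T cell markers 11 fell (12 adjusted over the list alone), including Thy1 (2.68-fold), Cd8a (2.12-fold), Ccr7 (1.99-fold) and Cd247 (1.91-fold). Of 15 natural killer cell markers 11 fell, adjusted over the list alone too, including Nkg7 (2.76-fold), Il2rb (2.58-fold), Klre1 (at least 1.71-fold) and Ccl5 (2.22-fold). Camera gave adjusted p = 2.54e-09 for B cells, 0.00134 for T cells and 0.000256 for natural killer cells. With an estimated correlation these became adjusted p = 0.39, 0.71 and 0.39.

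Dendritic cell markers and stromal and endothelial genes were lower as well. Of 14 dendritic cell markers 10 fell (11 adjusted over the list alone), including Fscn1 (4.67-fold, with probe sets that differed in call), Ly6d (3.91-fold), Batf3 (2.55-fold) and Irf8 (2.18-fold). Of 23 stromal and endothelial genes 18 fell (20 adjusted over the list alone), including Tie1 (2.58-fold), Madcam1 (2.27-fold), Bgn (2.25-fold) and Cdh5 (2.08-fold). Neutrophil and myeloid precursor genes rose: 14 of 19 passed and 0 fell, adjusted over the list alone too, with Lcn2 4.06-fold higher and Ms4a3, Fcnb and Mmp8 at least 3.95-fold, 2.22-fold and 2.36-fold higher. Wild-type arrays were uneven for the neutrophil list, with means of 8.74 in WT 3, 8.38 in WT 4, 7.13 in WT 5 and 6.91 in WT 6. Nix-null means ran from 8.96 to 9.78, so the size of the rise differed with the wild-type array compared. The camera values were adjusted p = 0.000594 for dendritic cells, 1.18e-05 for stroma and 2.61e-05 for neutrophils. With an estimated correlation they were adjusted p = 0.39, 0.39 and 0.46.

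Of 21 macrophage and monocyte markers 4 fell and 17 did not pass (3 fell adjusted over the list alone): Timd4 (2.38-fold), Csf1r (1.83-fold), C1qa (1.75-fold) and C1qb (1.4-fold). Timd4 and C1qb lost their call when some single array was left out. Of 20 megakaryocyte and platelet genes 6 fell (4 adjusted over the list alone), including Pdgfb (1.76-fold), Itgb3 (1.71-fold), Vwf (1.66-fold) and Gng11 (1.42-fold). Each of these 4 named genes lost its call when some single array was left out. Of 12 plasma cell genes 5 fell and 1 rose, adjusted over the list alone too: Irf4 fell 2.92-fold, Creb3l2 2.07-fold and Xbp1 1.6-fold, while Igha, the IgA heavy chain, rose 2.21-fold. None of these 3 lists passed camera (adjusted p = 0.23, 0.295 and 0.469, and adjusted p = 0.83 for each with an estimated correlation). Of 7 adipose genes 2 fell, Thrsp (3.07-fold, but 0.31 log2 units higher and not passing with quantile normalization repeated) and Lipe (1.58-fold), adjusted over the list alone too (camera adjusted p = 0.559, and adjusted p = 0.83 with an estimated correlation).

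Markers of pancreas differed strongly between arrays of each genotype: 0 of 14 rose and 0 fell, adjusted over the list alone too, with a list mean of 7.52 ± 3.58 in Nix-null and 8.69 ± 2.69 in wild-type arrays (SD, n = 4 each). The list mean was 12.86 in Nix_KO 3, 11.88 in WT 3 and 9.82 in WT 5, and between 5.30 and 7.24 in the other 5 arrays (camera adjusted p = 0.813, and adjusted p = 0.94 with an estimated correlation). WT 3 alone also held liver transcripts: Alb read an intensity of 3040 there (14.6 to 80.4 in the others), Ttr 2930 (9.63 to 193) and Apoa1 400 (8.68 to 16.9), genes looked at after the data were seen. The pancreas median of -1.52 rests on single arrays: without Nix_KO 3 it was -3.39 and the list passed camera (adjusted p = 0.00884), and another alternative turned its direction and passed as well (adjusted p from 0.00884 to 0.918 over the alternatives). Of the 4 sex-linked genes tested 0 rose and 0 fell, adjusted over the list alone too (camera adjusted p = 0.747, and adjusted p = 0.83 with an estimated correlation). Across the 26 lists, 13 passed at the preset correlation and 0 with an estimated one.

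**Figure D3:**
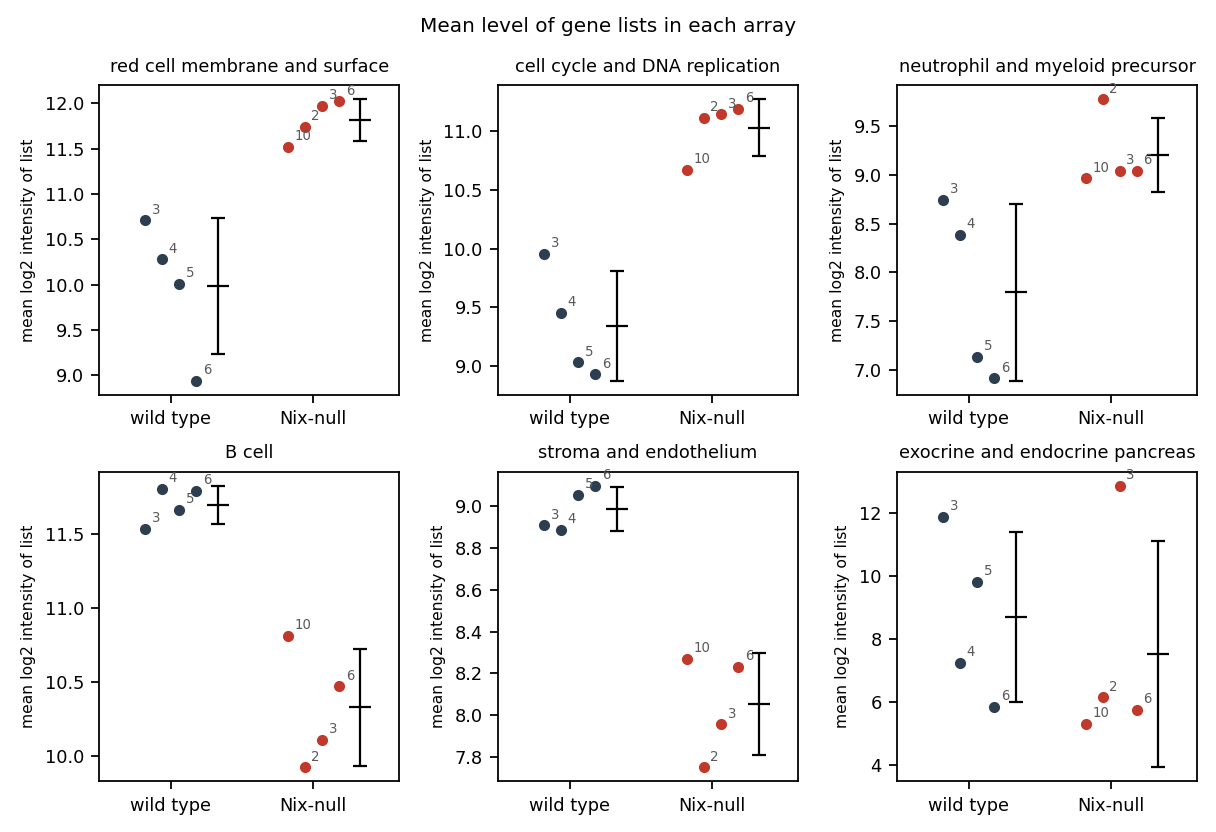
Mean log2 intensity (vertical axis) of 6 gene lists in each array, with a point per array marked by its title number and bars showing the mean ± SD of 4 arrays per genotype. Red cell membrane means were 11.81 in Nix-null and 9.99 in wild-type arrays, while pancreas means ran from 5.30 to 12.86, with high and low arrays in both genotypes.

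Arrays separated by genotype along the first principal component, which held 56.8% of the variance. Nix-null arrays lay between -83.7 and -21.1 on it, and wild-type arrays between 28.8 and 70.8. Pearson correlations between arrays over all tested probe sets were 0.938 to 0.968 within Nix-null, 0.970 to 0.986 within wild type and 0.872 to 0.955 between genotypes. These are correlations across probe sets, which are not independent replicates. Nix_KO 10 lay closest to the wild-type arrays, with a mean correlation of 0.945 with them.

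Genes neighbouring Bnip3l were examined because a knockout made in stem cells of another strain can carry sequence of that strain beside the target. Adamdec1, the most reduced gene, is the fifth tested gene to one side of Bnip3l, and Ccnb1ip1 also lies within 20 Mb. Within that window 84 of 203 genes (41.4%) were past the threshold, against 38.3% of the others, a difference that did not pass Fisher's exact test (odds ratio 1.14, 95% interval 0.848 to 1.52, p = 0.382). In a 5 Mb window the odds ratio was 1.56 (Fisher's exact p = 0.102). Without the arrays Nix_KO 3, WT 3 and WT 5, left out after seeing the data, it was 1.55 in the 20 Mb window (Fisher's exact p = 0.0135).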

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

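Each value below is a log2 intensity that lay far from the other 3 arrays of its genotype, by the ratio of its gap to the range of the 4 arrays. Of 304 such groups examined 15 stood out, against 15.2 that chance gives at 1 in 20, a number that chance alone can give. They were not spread evenly over the arrays: most of those in the wild-type group were low values of WT 3, which also held pancreatic and liver transcripts. The cause of that was not tested. The pancreas value below is also an exception, since the pancreatic gene Cela2a read an intensity of 15500 in that array against 21.7 to 90.4 in the other Nix-null arrays. In the Nix-null group, St6galnac1 was low in Nix_KO 6 (5.32, others 6.985 to 7.201), Ang was high in Nix_KO 3 (4.43, others 1.599 to 2.032) and Ms4a3 was high in Nix_KO 2 (9.07, others 7.06 to 7.39). The mean of the neutrophil list was also high in Nix_KO 2 (9.78, others 8.96 to 9.05). In Nix_KO 10 the mean of the cell cycle list was low (10.67, others 11.11 to 11.19) and that of the dendritic cell list high (8.48, others 7.80 to 7.83). The mean of the pancreas list was high in Nix_KO 3 (12.86, others 5.30 to 6.15).

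In the wild-type group, WT 3 was low for Dph5 (9.37, others 9.68 to 9.74), Cd79a (13.55, others 13.77 to 13.79), Thy1 (10.48, others 10.96 to 11.03), Klre1 (5.41, others 5.86 to 5.92), C1qa (11.76, others 11.91 to 11.93) and Batf3 (7.84, others 8.40 to 8.46). Slc4a1 was low in WT 6 (13.86, others 14.59 to 14.67), and Itgb3 was high in WT 4 (9.01, others 8.49 to 8.57).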

How the results depend on the processing

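The alternatives that leave out arrays with pancreatic or with Xist and Y-linked signal, use Kdm5d as covariate, or count only all-or-none genes (also with low values raised to 5) or genes changed at least 4-fold, were chosen after seeing the data. The 4 arrays per genotype, and signal near background for weak probe sets, limit these results; the cause of a difference between settings was not tested. Of the lists that did not pass as reported, the immediate-early list passed under 7 alternatives (no filter, the replicate block, probe sets averaged, Kdm5d as covariate, and without Nix_KO 10, WT 3 or the arrays with Xist and Y-linked signal; adjusted p from 0.00317 to 0.294 over all alternatives). The macrophage list passed without a filter and without Nix_KO 6 (0.0146 to 0.49), the megakaryocyte list without a filter and without WT 6 (0.0182 to 0.665), and with the block the plasma cell list (0.0378 to 0.744) and the autophagy list (0.022 to 0.526). The pancreas list passed in opposite directions, lower without Nix_KO 3 (-3.39, 0.00884) and higher with the block (0.513, 0.00971). Of those that passed, oxidative phosphorylation was lost without a filter, with array weights and with the block, and the T cell list with array weights. The medians of the 6 main lists kept their sign under every alternative run, and 4 of the 123 named genes (Ang, Bak1, Casp9 and Thrsp) reversed under some. With an estimated correlation in camera the 4 raised main lists, with medians of 1.62, 2.10, 1.54 and 1.70, no longer passed (adjusted p = 0.465, 0.388, 0.388 and 0.388). A plain unequal-variance test called 2174 probe sets (1130 higher, 1044 lower) and 1941 genes (864 higher, 1077 lower). The title numbers 3 and 6 gave correlations of deviations of 0.252 and 0.147, with up to 0.168 and 0.229 for other numbers; with only these pairs the arrays were not treated as paired. With the replicate block, which leaves few residual degrees of freedom, 1 probe set (0 higher, 1 lower) and 1441 genes (772 higher, 669 lower) passed, and the log2 changes became 0.513 for pancreas (past the threshold), -0.164 for sex-linked genes and 0.081 for Casp9. Leaving out single arrays gave 3996 (without WT 6) to 6993 changed probe sets and 2096 (without WT 4) to 4221 lower ones, with 4075 changed without WT 4, 2107 lower without WT 6 and 2529 lower without WT 5. For Bnip3l it gave 0.373 to 0.788 for its probe set C (adjusted p = 0.03 without Nix_KO 10) and -0.712 to -0.303 for B (adjusted p = 0.0426 without Nix_KO 3). It gave -0.569 to 0.9 for the sex-linked list, -0.218 to 0.0109 for the interferon list and -0.247 to 0.0647 for Bak1. Quantile normalization repeated turned p53 targets (0.00548), interferon genes (0.0158) and Thrsp (0.309), and median centring p53 targets (0.0379), interferon genes (0.0443) and Bak1 (0.0391). Ang was 0.005 without a filter, Casp9 0.012 with probe sets averaged, and the sex-linked list -0.123 with low values raised to 5. Without the arrays with pancreatic signal 690 probe sets (500 higher, 190 lower) and 1684 genes (846 higher, 838 lower) passed, Bak1 was 0.118, and the odds ratio near Bnip3l was 1.55 (Fisher's exact p = 0.0135, from 0.0553 to 0.941 under the other alternatives that counted all changed genes within 20 Mb). Without the arrays with Xist and Y-linked signal Bak1 was 0.0146. Counting only genes changed at least 4-fold, the odds ratio near Bnip3l was 3.08 (Fisher's exact p = 0.00165). Of 117 named genes past the threshold, 78 kept their call under every alternative other than the block and the plain test; 11 lost it without some single array (Bcl2, C1qb, Cycs, Gng11, Itgb3, Ndufa5, Ndufv2, Pdgfb, Timd4, Vwf and Zmat3). For named genes 2384 comparisons with the values reported kept the call, 178 lost it, 3 gained it and 8 reversed; for lists 528 kept it, 17 lost it, 14 gained it and 12 reversed.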

Other observations

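All tests in this part were chosen after the results were seen, except the count of splits and 2 of the counts of genes near Bnip3l. In all, 17 groups of genes, put together by symbol or by known function, were tested with camera. All 10 tested genes of MHC class II antigen presentation fell (median log2 change -1.34, camera adjusted p = 0.000142). Among them Ciita, the master regulator of the class, fell 3.14-fold and H2-DMa, which loads peptides, 3.10-fold. Of 10 MHC class I genes 8 fell, including the peptide transporter genes Tap1 (2.35-fold) and Tap2 (2.65-fold), and 1 rose, H2-T24 (camera adjusted p = 0.0132). Of 18 interleukin receptor genes 10 fell and 1 rose, with Il4ra 3.39-fold lower (camera adjusted p = 0.00617). With an estimated correlation the adjusted p was 0.5 for each of these groups.

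Centromere proteins were higher: 17 of 20 rose and 0 fell, with Cenpp 5.62-fold and Cenpf 5.54-fold higher (camera adjusted p = 7.83e-10, and adjusted p = 0.5 with an estimated correlation). Of 37 proteasome genes 7 rose and 3 fell (camera adjusted p = 0.00583, and adjusted p = 0.57 with an estimated correlation). The 3 that fell were Psmb8 (2.32-fold), Psmb9 (2.25-fold) and Psmb10 (2.38-fold), the catalytic subunits of the immunoproteasome. Of 36 tripartite motif genes 15 fell and 4 rose (camera adjusted p = 0.152, and adjusted p = 0.5 with an estimated correlation). The medians of all these groups kept their sign when the arrays were quantile-normalized again or median-centred.

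The real grouping was compared with all 35 ways to split the 8 arrays into 4 and 4. Only 1 of the 35, the real one, called as many as 6711 probe sets (the highest other called 6) or 4227 genes (the highest other called 3). A share of 1 in 35, or 0.0286, is the smallest that these splits can give, so they cannot exclude chance. The real split was likewise alone among the 35 in the size of 4 list medians. These were erythroid regulators (1.62, highest other 1.24), the red cell membrane (2.10, highest other 1.70), haemoglobin, haem and iron (1.54, highest other 1.02) and the cell cycle (1.70, highest other 1.45). For the BCL2 family 3 of the 35 splits moved the median as far (-0.145, highest other 0.226 in size), and for caspases and death factors 4 did (-0.174, highest other 0.215 in size), so chance is not excluded for either.

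Erythroid genes rose while lymphoid genes fell. A constant scaling of the arrays would move lists alike, but the red cell membrane list rose by 3.19 log2 units relative to the B cell list, with no overlap of arrays. Even dilution by red cell precursors would lower all other cell types alike, but B cell genes changed by -0.971 relative to macrophage genes. Exact permutation gave p = 0.0286, the smallest possible, as for all 6 such differences computed. The pair was picked after the list changes were seen, and all 6 differences include the B cell list. These p-values are therefore not independent support against dilution. Of 19 neutrophil genes 14 rose and 0 fell, though that list did not pass camera with an estimated correlation (adjusted p = 0.46). The neutrophil list mean of WT 3 (8.74) also lay close to the lowest Nix-null mean (8.96), while WT 6 read 6.91. Pancreatic tissue in 3 arrays does not account for it, since the red cell membrane median was 2.57 without them. An effect of genotype on the cell content of the spleen stays open; it was not tested, as no cell counts were used here.

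In 21 genes the 4 arrays of each genotype lay at least 1.5 log2 units apart, a gap picked after looking at the values; 20 were higher and 1, Adamdec1, lower. The gap uses readings below 5; with those set to 5, 20 of the 21 stayed apart and Fn3krp did not. A candidate explanation is sequence of another strain beside the target gene, which predicts such genes near Bnip3l: 2 of them, Adamdec1 and Ccnb1ip1, lay within 20 Mb, an odds ratio of 5.64 (95% interval 0.633 to 23.6) that missed the threshold (Fisher's exact p = 0.0566; 5.95 and p = 0.0518 with readings below 5 set to 5). It was 1 of 5 such counts, of which the 2 chosen in advance missed it too; the last chosen, of genes changed at least 4-fold, gave 3.08 (Fisher's exact p = 0.00165, adjusted p = 0.00825 over the 5, against 0.129 to 0.382 for the others). Cell composition stays open: Adamdec1 fell 4.83 log2 units further than the most reduced of 192 cell markers, Fscn1, by the deposited values, and 2.82 with values below 5 set to 5. Both meet the bound of 2 units first set for excluding composition, but it covers 1 of the 21 genes; the demand that at least 0.5 of them lie that far beyond every marker was added after the value was seen, and 3 did by the deposited values but only Adamdec1 with values below 5 set to 5. The loss of a rare cell type outside the lists could also give such a fall. A variant under single probe sets also stays open, since only 4 of the 21 genes had another probe set past the filter, with a median change 0.614 times that of the first.

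Xist, a transcript of female cells, was found at high intensity (1600 and 1730) beside Y-linked transcripts in Nix_KO 10 and WT 5. Xist stood there at 18.1% and 19.6% of its mean in the 4 arrays with Kdm5d near background. Kdm5d read intensities of 170 and 191, against 212 in Nix_KO 6 and 296 in WT 6. Weaker mixed signal was seen elsewhere: WT 6 read Xist at 239, 2.7% of that mean, against 28.5 in Nix_KO 6. Nix_KO 3, among those 4 arrays, read the Y-linked Eif2s3y at 68.6, against 7.75 to 16.7 in the others. WT 6 may therefore not be a clean reference for WT 5. RNA of a wild-type spleen in Nix_KO 10 stays open. It would bring Adamdec1, which was at 0.508% of its wild-type mean there by a reading below 5, so at most 2.98%, far under the Xist share. But of 5 genes at least 1.5 log2 units lower in the 3 other Nix-null arrays, picked without Nix_KO 10 and then kept if at least 5 in all Nix-null arrays, 2 read below the level that share would give, with a median difference of 0.254 (SD 0.351). RNA of a Nix-null spleen in WT 5, at the Xist share, is argued against: of 14 genes raised by at least 1.5 log2 units against the 3 other wild-type arrays, picked without WT 5 and then kept if at least 5 in all wild-type arrays, 13 read below the level that share would give. Their median difference from that level was -0.987 log2 units (SD 0.478); Armc8 was the exception. Ccnb1ip1, at 4.80% of its Nix-null mean, read below 5 there, so it only shows a share of at most 9.48% and does not decide by the bound of 4.9 first set for it. RNA of a female spleen of the same genotype may be present, and would lower Y-linked genes: Kdm5d was 19.8% lower than in Nix_KO 6 and 35.5% lower than in WT 6, but Uty was higher in Nix_KO 10 than in Nix_KO 6, and single arrays cannot decide it.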
